A study of Homo sapiens with 9 samples.

How the data were processed

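DMS-MaP was applied to H9 human embryonic stem cells and to neural precursor cells derived from H9. Per the labels, 2 stem cell libraries and 3 precursor libraries were treated with 4% DMS, and 2 libraries of each cell type were treated with DMSO as the control. The stem cells are day 0 and the precursors day 7, per the labels' protocols and the series description. Per the labels, RNA was extracted with Trizol, reverse transcribed and made into Illumina libraries. Bowtie 0.12.8 and the human assembly GRCh38 are named in the submitters' processing notes. The mutation caller, the minimum coverage, the choice of isoform and the way replicates were combined are not given in the sources used here.

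A single table held the values, with a row for each transcript position and stage. Per the file headers, it gives a control mutation rate, a treated mutation rate, their difference, a lower and an upper limit, and a normalized reactivity. The deposited normalized reactivity is a score between 0 and 1. The other columns are mutation rates or their limits, which are fractions, and are printed here as percentages. Checked on the values of the stages used, the difference equalled treated minus control in 100% of rows, with a tolerance of 1e-09. The limits equalled the 5th and 95th percentiles of the difference over the listed positions of a transcript at a stage, and the score equalled the difference scaled between these limits and clipped at 0 and 1. Only A and C positions and only positions with a treated rate above the control rate are listed. The score therefore compares positions within a transcript at a stage, and its mean depends on which positions set the limits, so a change of modification shared by all positions of a transcript leaves it unchanged.

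Each position has a single control rate and a single treated rate per stage with no library named, so no value can be tied to a library. No test between stages, no standard deviation between libraries and no p-value could be given. The read depth is unknown, and no counts were inferred from the rates. The tests planned with limma over libraries were not applied for this reason, and differences are given as values, as the plan fixed before the data were examined provides for pooled columns.

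The table has 4 stages, H9, D0, D7 and a further stage that matches none named in the series description and was not used. The stage names do not settle which cell type D0 and D7 are, because the labels give D0 as the stem cells while the table lists H9 apart. The stage was never inferred from the values, and the comparisons H9 to D0, H9 to D7 and D0 to D7 were all made. They share stages, so they are not independent of each other.

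For each pair, values were taken at positions listed at both stages. A transcript was eligible with at least 100 shared positions. Computed per transcript were the mean score at each stage, Pearson and Spearman correlations across positions, the Gini index and the log2 ratio of the mean background-subtracted rate. Windows of 50 nucleotides, counted from the first base of the transcript as the table numbers it, needed at least 10 shared positions. A position counted as different with a score difference above 0.5. As a reference without agreement between positions, scores were shuffled 20 times within transcript and base. A was compared with C in transcripts with at least 20 listed positions of each base. Intervals of shares are exact Clopper-Pearson 95% intervals and intervals of medians come from order statistics. Those of the A to C ratio in the rRNAs and of the change in contrast between position sets come from 2000 bootstrap draws. All of them treat transcripts or positions as independent, which they are not.

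Gene groups came from 17 lists fixed before the data were examined. They cover cytosolic ribosomal proteins, translation factors, pluripotency, neural precursor and neuronal markers, other germ layers and contaminating lineages, RNA-binding proteins and splicing factors, glycolysis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded RNAs, cytoskeleton, chaperones and heat shock, histones and chromatin, cell cycle and replication, mRNAs with textbook regulatory RNA structures, structural noncoding RNAs, and RNA structure and modification machinery. A list with at least 5 eligible members was summarised by its median difference and the percentile of that median among 10000 random lists of the same size, matched in 5 bins of mean reactivity. Random lists were drawn from all eligible transcripts, the members of the list included. For the large list of ribosomal proteins they therefore overlap much with the list itself. Named transcripts followed a rule also fixed beforehand. It takes the 6 largest positive and 6 largest negative differences of mean reactivity, the 5 lowest and 5 highest correlations, up to 3 eligible members of each list with the most shared positions, and the 3 windows that differed most in each direction with at most 1 per transcript. A few other members of the lists and the rRNA values were named after they were seen, among them CFL1 and MYL6, the single strongest rRNA positions and the extremes of the rate ratio. A transcript that the rule selects is not reported here.

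Names were matched to NCBI RefSeq on GRCh38.p14, and 254 of 258 names had a match, 13 of them through an older symbol. The 3 rRNA names and SHFM1 had none. Gene positions are those of RefSeq, while positions within a transcript are the table's own. Among the names printed, ATP5B, ATP5A1, GNB2L1, H2AFZ and H3F3A are older symbols of ATP5F1B, ATP5F1A, RACK1, H2AZ1 and H3-3A. Reactivity by 5′ UTR, coding region and 3′ UTR was not analysed here, because no transcript sequence or exon annotation was used. The DMS against DMSO comparison is given as values only, because the table lists only positions where the treated rate is the higher one.

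Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9. The comparison of transcripts and of lists was tested on simulated data built on the 111 transcripts of the H9 to D0 comparison. All 20 transcripts with a planted shift of 0.1 ranked among the top 20, a planted correlation of 0.5 returned a median of 0.508, and 3 of 40 lists without a shift lay outside the central 95% of random lists. The simulation kept the listed positions and the scale fixed, and its correlation was above the median of 0.203 in the data. It therefore checks the calculations and not how reliable the reported rankings are. Alternatives covered the minimum number of positions, medians instead of means, window length, thresholds, scaling of the stages to the same median, rescaling on the shared positions, A or C positions alone, positions with a control rate of at most 0.2% at both stages and the unscaled rates.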

Results

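RNA structure was probed with dimethyl sulfate mutational profiling (DMS-MaP) in H9 human embryonic stem cells and in neural precursor cells derived from them. Dimethyl sulfate (DMS) methylates adenines and cytosines whose base-pairing face is free, and a reverse transcriptase reads the methylated bases as mutations, so a high mutation rate marks an accessible base. The labels describe 9 libraries. The stem cells have 2 libraries treated with 4% DMS and 2 treated with the solvent DMSO, and the precursors have 3 DMS libraries and 2 DMSO libraries. The values analysed give a single control rate and a single treated rate per transcript position and stage. Which of the libraries went into each stage is not given in the sources used here. There were therefore no replicates to set against any difference between stages, and no test between stages was made. The number of reads behind a position is unknown.

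The table names its stages H9, D0 and D7, together with a further stage that was not used here. H9 is the name the labels give to the stem cells. The series description uses D0 for the stem cells and D7 for the precursors, while the table lists H9 and D0 apart, so the cell type of D0 and D7 is not assigned here. The change from stem cell to precursor is H9 to D0, H9 to D7 or D0 to D7, depending on the reading, and all 3 comparisons are given under the table's own stage names. If D0 were the precursors, D7 could be a later stage, such as neurons derived from them, which the labels do not describe. Reactivity is the background-subtracted mutation rate scaled from 0 to 1 within a transcript at a stage. Mean reactivity is the average over the positions of a transcript that were listed at both stages compared, for transcripts with at least 100 such positions. Gene coordinates are those of GRCh38.

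H9 had 224 transcripts with 54053 listed positions, D0 had 192 transcripts with 46473 positions, and D7 had 133 transcripts with 30952 positions. All 3 stages shared 114 transcripts. Messenger RNAs of cytosolic ribosomal proteins were the largest group, with 60 listed at H9, 58 at D0 and 58 at D7. Oxidative phosphorylation mRNAs encoded in the nucleus numbered 20 at H9, 16 at D0 and 12 at D7. The corresponding numbers were 12, 10 and 10 for cytoskeletal mRNAs, 9, 11 and 5 for translation factors, 9, 7 and 2 for chaperones, and 7, 6 and 3 for glycolytic enzymes. Listing depends on filters of the submitters that are not given in the sources used here, so presence in the table is not a measure of expression.

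Few transcripts with a known link to cell identity were listed. The neuronal list had UCHL1, a ubiquitin hydrolase abundant in neurons, at H9. TUBB3, the neuronal class III β-tubulin, was listed at D0 and D7, and STMN2, a microtubule regulator of growing axons, only at D7. The intermediate filament mRNA VIM and the retinoic acid-binding protein mRNA CRABP1 were listed at D0 and D7 but not at H9. VIM was the only listed member of the neural precursor list, and CRABP1 the only one of the pluripotency list. The pluripotency list thus had 0 members listed at H9. Only 3 transcripts were listed at D7 alone among the stages used, and they were STMN2, NREP and TMSB15A. IFITM1 and UCHL1 were among the 60 transcripts listed at H9 alone. For TUBB3 the mean reactivity over its shared positions was 0.257 at D0 and 0.349 at D7, and for VIM it was 0.307 and 0.346. CRABP1 had 0.256 at D0 and 0.299 at D7. These values hold for the scale as deposited. Rescaled on the positions shared by D0 and D7, the difference of VIM was −0.009, while TUBB3 and CRABP1 stayed higher at D7, by 0.105 and 0.086.

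The 18S ribosomal RNA gave the most alike profiles between stages. The Pearson correlation of reactivity across positions of 18S rRNA was 0.909 between H9 and D0 over 511 positions, 0.852 between H9 and D7 over 673 positions, and 0.767 between D0 and D7 over 526 positions. It was the highest of all eligible transcripts in each comparison. The 28S rRNA gave 0.451, 0.484 and 0.541, and ranked 5th, 3rd and 2nd. Correlations of this kind are taken across positions of a transcript, which are not independent replicates.

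Between H9 and D0, mean reactivity differed little in sum, and the largest differences of single transcripts went both ways. Of 111 eligible transcripts, 50 had a higher mean reactivity at D0 and 61 a lower one, with a median difference of −0.00498 and a range from −0.105 to 0.161. The largest positive difference was in RPL23A, a protein of the large ribosomal subunit (chromosome 17, 28719985 to 28724359), with a mean reactivity of 0.18 at H9 and 0.341 at D0 over 128 positions. RPL17 (chromosome 18, 49488481 to 49492465) followed with 0.162 and 0.321. CKS1B, a regulatory subunit of cyclin-dependent kinases, had 0.214 and 0.361. The ATP synthase β subunit mRNA ATP5B had 0.239 and 0.382, the glycolytic enzyme mRNA PGAM1 had 0.210 and 0.322, and the α-tubulin mRNA TUBA1A (chromosome 12, 49184795 to 49189080) had 0.272 and 0.373. The direction of RPL17 turned to −0.041 when reactivity was rescaled on the shared positions, and the differences of RPL23A, PGAM1, CKS1B and ATP5B shrank to 0.020, 0.014, 0.043 and 0.046, whereas TUBA1A kept 0.091.

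The largest negative differences from H9 to D0 were in RPS15 (chromosome 19, 1438396 to 1440495), with a mean reactivity of 0.368 at H9 and 0.264 at D0, and in RPL4, with 0.415 and 0.319. GSTP1, a glutathione transferase, had 0.328 and 0.232, RPL23 had 0.379 and 0.288, and the mitochondrial single-stranded DNA-binding protein mRNA SSBP1 had 0.376 and 0.288. RPS6, whose protein is phosphorylated downstream of mTOR signalling, had 0.426 and 0.342. On the rescaled values all 6 stayed lower at D0, with differences between −0.072 for RPS6 and −0.001 for RPL23.

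**Figure D1:**
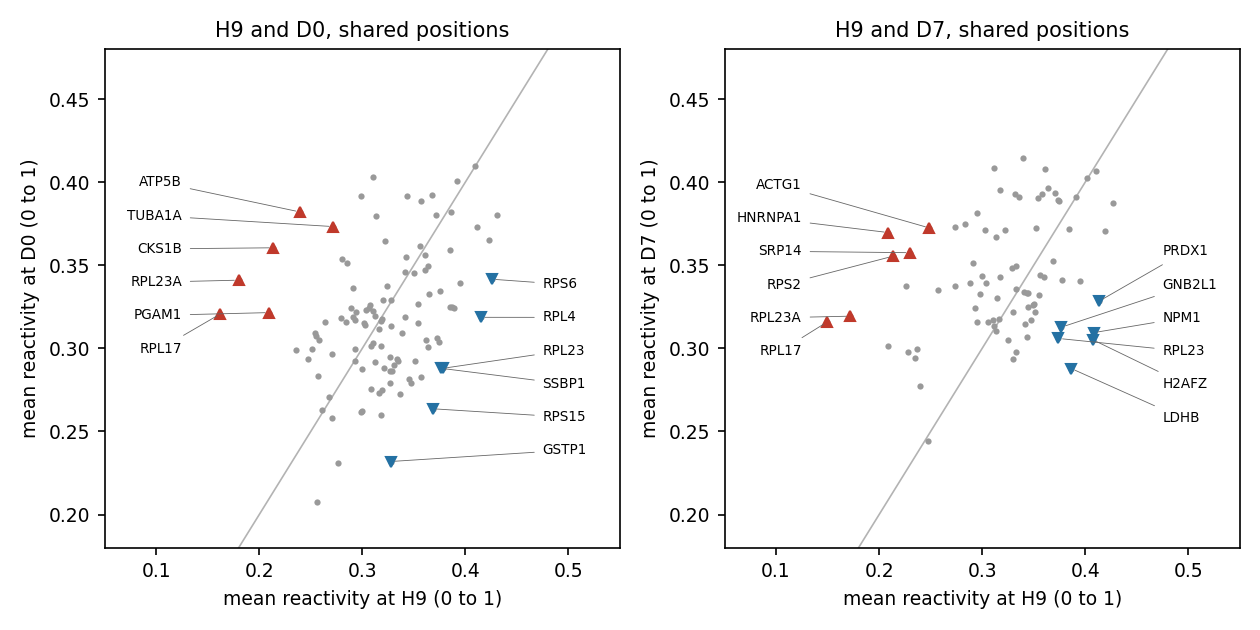
Mean reactivity (0 to 1) of each eligible transcript over its shared positions, with H9 on the x axis and D0 (left) or D7 (right) on the y axis; the grey line marks equality, and triangles mark the 6 largest positive and 6 largest negative differences. RPL23A and RPL17 lie far above the line in both panels, with mean reactivities under 0.2 at H9 and above 0.3 at the other stage.

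By gene group, the 48 eligible ribosomal protein mRNAs had a median difference of −0.022 from H9 to D0, with 18 higher and 30 lower, which lay at the 9.12th percentile of 10000 random lists matched on mean reactivity. After rescaling, the median was −0.0027 at the 75.8th percentile, with 21 higher and 27 lower. RPL3 had a mean reactivity of 0.365 at H9 and 0.333 at D0, and RPL13A had 0.336 and 0.272. Of 7 translation factor mRNAs, 6 were higher at D0, with a median difference of 0.019 at the 91.8th percentile, and 4 of 7 were higher after rescaling. EEF1A1 had 0.409 and 0.410, EEF1G had 0.322 and 0.365, and the ribosomal scaffold mRNA GNB2L1 had 0.361 and 0.347. The 5 glycolytic mRNAs had a median difference of −0.048 at the 7.23th percentile, with 2 higher and 3 lower, and of −0.013 at the 35.9th percentile after rescaling. Among them GAPDH had 0.431 and 0.380, ENO1 had 0.327 and 0.279, and LDHB had 0.372 and 0.380. Chaperone mRNAs, of which 4 of 5 were higher at D0 and 3 of 5 after rescaling, had a median difference of 0.014 at the 57.7th percentile. HSP90AA1 had 0.319 and 0.318, HSP90AB1 had 0.301 and 0.315, and HSPA8 had 0.271 and 0.297. None of these lists lay outside the central 95% of its random lists, on either scale.

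Taken as a list, cytoskeletal mRNAs stood apart in their mutation rate between H9 and D0. Over the 7 eligible members the background-subtracted rate at D0 differed from that at H9 by a median of −0.58 on the log2 scale, below all of the 10000 random lists, against −0.04 over all transcripts. The comparison of lists by rate was added after the data were seen, while the plan covered mean reactivity only. This was the most extreme percentile among all lists, comparisons and measures, so it is not a test result. The random lists were matched on mean reactivity, not on rate or read depth. Whether read depth or the listing of positions plays a part here was not tested. The rate of TUBA1A was 0.419% at H9 and 0.211% at D0, that of the γ-actin mRNA ACTG1 was 0.479% and 0.253%, and that of the β-actin mRNA ACTB was 0.349% and 0.232%. The actin-severing factor mRNA CFL1 had 0.573% and 0.383%. TUBA1B, with 0.248% and 0.223%, and TMSB4X, with 0.223% and 0.186%, differed less, at −0.15 and −0.26 on the log2 scale. The central 95% of random list medians ran from −0.21 to 0.14. Low ratios also occurred outside the list, at −0.38 in 18S rRNA, −0.42 in 28S rRNA and −0.52 in RPS19. Over all 111 transcripts, the rate was lower at D0 in 62 and higher in 49. Of the 7 members, only MYL6 had a higher rate at D0. Their scaled mean reactivity did not differ in the same way, with a median difference of 0.002, 4 members higher and 3 lower, at the 70.4th percentile. Rescaled on shared positions, the median difference was 0.043 with 5 higher and 2 lower, at the 99.6th percentile and above the central 95% of random lists, which ran from −0.051 to 0.024. ACTB and ACTG1, and the α-tubulins TUBA1A and TUBA1B, encode near-identical proteins. How reads from stretches that such mRNAs share were assigned is not given in the sources used here.

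Lists with fewer than 5 eligible members gave values for their named members. From H9 to D0, the nucleolar mRNAs NPM1 and NCL had mean reactivities of 0.387 and 0.382, and of 0.293 and 0.30. The splicing factor mRNA HNRNPA1 had 0.258 and 0.305. ATP5A1 had 0.316 and 0.273, and UQCRH had 0.280 and 0.318. The histone variant mRNA H2AFZ had 0.389 at H9 and 0.324 at D0, SET had 0.308 and 0.301, and HMGN1 had 0.291 and 0.336. Among mRNAs with known regulatory RNA structures, the ferritin mRNAs FTL and FTH1, which carry an iron-responsive element, had 0.327 and 0.295, and 0.318 and 0.301. OAZ1, which is translated through a programmed frameshift, had 0.294 and 0.322. Rescaled on shared positions, NCL, HNRNPA1, ATP5A1, UQCRH, HMGN1, FTH1 and OAZ1 changed direction, at −0.003, −0.009, 0.008, −0.065, −0.068, 0.016 and −0.084. NPM1, H2AFZ, SET and FTL kept theirs. Over all eligible transcripts of H9 to D0, 35 of 111 changed direction when rescaled. CKS1B was the only eligible member of the cell cycle list. Of the structural noncoding RNA list only GAS5 was listed, with a mean reactivity of 0.327 over 111 positions at H9, 0.308 over 154 positions at D0 and 0.341 over 75 positions at D7, and of the RNA structure and modification machinery only HNRNPC, at H9. The lists of mitochondrially encoded RNAs and of other germ layers had 0 members listed.

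Position by position, the mRNA profiles of H9 and D0 resembled each other weakly. Without rRNA, the median Pearson correlation over 109 transcripts was 0.203 (95% interval of the median 0.173 to 0.228), and shuffling positions within transcript and base brought it to 0.005. The highest values after 18S rRNA were those of PTMA at 0.505, HNRNPA1P10 at 0.497 and TMSB4X at 0.485. HNRNPA1P10 is a pseudogene of HNRNPA1, and how reads were divided between such copies is not known here. SSBP1 at −0.050, APEX1 at −0.037, EIF3E at −0.021, VDAC2 at −0.009 and FDPS at 0.007 were the lowest. The treated rate before subtraction correlated far better, with a median of 0.778, as did the control rate, with 0.829. Reactivity differed by more than 0.5 at 3753 of 25849 shared positions, or 14.5%, against 19.2% after shuffling.

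**Figure D2:**
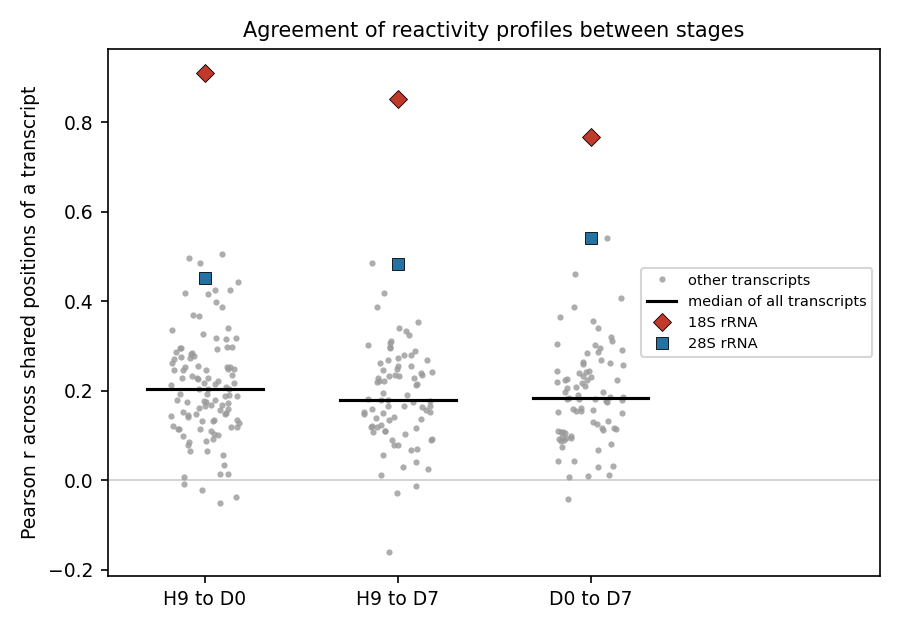
Pearson correlation of reactivity across the shared positions of each eligible transcript (y axis) for the 3 pairs of stages (x axis), with grey points for single transcripts, a black line for their median, a diamond for 18S rRNA and a square for 28S rRNA. The 18S rRNA lies at 0.909, 0.852 and 0.767, while the median without rRNA is 0.203, 0.179 and 0.18.

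Of 1301 windows of 50 nucleotides, 603 (46.3%) had a higher mean reactivity at D0. The largest positive differences were at nucleotides 1651 to 1700 of ATP5B, with 0.183 at H9 and 0.554 at D0, at 301 to 350 of CKS1B, with 0.058 and 0.419, and at 951 to 1000 of TUBA1A, with 0.246 and 0.569. In each of them 8 or 9 of 10 positions were higher at D0, a count that largely follows from picking windows by their difference. Scores spread widely within a window, with a standard deviation across positions of 0.213 at H9 and 0.299 at D0 in that of ATP5B. No shuffled reference was made for windows, so how large a difference arises without any change is not known. The largest negative differences were at 51 to 100 of RPL35A, with 0.565 and 0.196, at 101 to 150 of RPL11, with 0.570 and 0.247, and at 451 to 500 of RPL36, with 0.50 and 0.188. After rescaling on shared positions these differences were 0.290, 0.319 and 0.318, and −0.345, −0.284 and −0.297. The Gini index, which rises as reactivity is concentrated in fewer positions, was higher at D0 in 74 of 111 transcripts, with medians of 0.455 at H9 and 0.461 at D0. On the unscaled rate that share was 48.6% instead of 66.7%.

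From H9 to D7, every transcript compared had a higher mutation rate at D7. The background-subtracted rate at shared positions was higher at D7 in 83 of 83 transcripts, with a median ratio of 2.18. The log2 ratio was 1.86 for NPM1 and 1.84 for the peroxiredoxin mRNA PRDX1, whose rates went from 0.308% to 1.12% and from 0.306% to 1.09%. It was 1.18 for 18S rRNA and 0.29 for 28S rRNA. At the low end of the mRNAs it was 0.21 for TUBA1A, 0.35 for PTMA, 0.46 for ACTG1 and 0.50 for RPS2 and for CFL1, and it was 0.73 for ACTB. The 7 cytoskeletal mRNAs had a median of 0.73, which lay at the 1.54th percentile of random lists, and TUBA1B among them had 1.43. Glycolytic mRNAs had 1.24 for GAPDH, 1.51 for LDHB and 1.72 for TPI1. Oxidative phosphorylation mRNAs had 1.53 for ATP5B, 1.55 for ATP5A1 and 1.36 for COX7C.

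**Figure D3:**
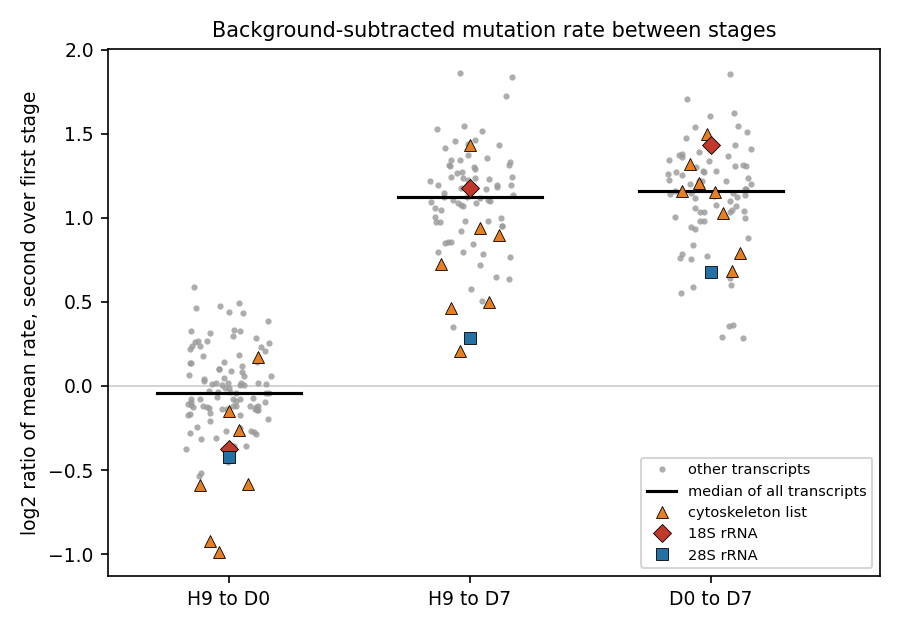
Log2 ratio of the mean background-subtracted mutation rate, second over first stage (y axis), for each eligible transcript in the 3 pairs of stages (x axis), with the cytoskeleton list as triangles, 18S rRNA as a diamond, 28S rRNA as a square and the median as a black line. All transcripts lie above 0 in both comparisons with D7, and the median is −0.04 between H9 and D0.

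In scaled reactivity, 51 of 83 transcripts were higher at D7 than at H9 and 32 lower, with a median difference of 0.016. Rescaled on shared positions, 34 of 83 were higher, so the balance depends on the scale. RPL17 had a mean reactivity of 0.149 at H9 and 0.316 at D7, HNRNPA1 had 0.209 and 0.370, and RPL23A had 0.172 and 0.319. These 3 turned to −0.074, −0.040 and −0.018 on the rescaled values. RPS2 (chromosome 16, 1962058 to 1964826) had 0.214 and 0.356, SRP14, a protein of the signal recognition particle, had 0.230 and 0.358, and ACTG1 had 0.249 and 0.372, and their rescaled differences were 0.047, 0.020 and 0.060.

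The largest negative differences from H9 to D7 kept their sign after rescaling. H2AFZ (chromosome 4, 99948088 to 99950275) had a mean reactivity of 0.407 at H9 and 0.305 at D7, NPM1 (chromosome 5, 171387116 to 171410900) had 0.408 and 0.309, and the lactate dehydrogenase mRNA LDHB (chromosome 12, 21635342 to 21657842) had 0.387 and 0.288. Their rescaled differences were −0.054, −0.122 and −0.110. PRDX1 had 0.414 and 0.329, RPL23 had 0.374 and 0.306, and GNB2L1 had 0.377 and 0.313, with rescaled differences of −0.051, −0.033 and −0.067. The 3 eligible glycolytic mRNAs were all lower at D7, also after rescaling, with GAPDH at 0.419 and 0.371 and TPI1 at 0.345 and 0.325.

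The 49 ribosomal protein mRNAs had a median difference of 0.019 from H9 to D7, with 31 higher and 18 lower, at the 96.3th percentile of random lists. The median turned to −0.015 after rescaling, at the 26.1th percentile. These mRNAs were 49 of the 83 eligible transcripts, so the random lists consisted largely of the same mRNAs. Both percentiles thus say little about ribosomal protein mRNAs against others. RPL4 had mean reactivities of 0.395 and 0.341, RPL3 had 0.370 and 0.394, and RPL13A had 0.342 and 0.314. The cytoskeletal mRNAs had a median difference of 0.059 at the 91.4th percentile, with 5 of 7 higher. After rescaling it was 0.037, at the 99.0th percentile with 6 of 7 higher. ACTB had 0.273 and 0.338, TUBA1A had 0.274 and 0.373, and TUBA1B had 0.351 and 0.322. In smaller lists, EEF1G had 0.305 and 0.316, EEF1B2 had 0.283 and 0.375, HSP90AA1 had 0.293 and 0.324, and HSP90AB1 had 0.257 and 0.335. H3F3A had 0.248 at H9 and 0.244 at D7, ATP5B had 0.228 and 0.298, FTL had 0.311 and 0.313, and FTH1 had 0.330 and 0.322. Rescaled, RPL3, HSP90AA1, HSP90AB1, H3F3A, ATP5B, FTL and FTH1 changed direction, at −0.035, −0.013, −0.004, 0.049, −0.024, −0.053 and 0.001. The other transcripts named in this paragraph kept theirs. Over all eligible transcripts of H9 to D7, 27 of 83 changed direction when rescaled.

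The median correlation between H9 and D7 without rRNA was 0.179 (95% interval 0.153 to 0.222) over 81 transcripts, and 15.3% of 19139 shared positions differed by more than 0.5, against 19.7% after shuffling. After 18S rRNA, the highest correlations were those of RPL41 at 0.486, 28S rRNA at 0.484, TMSB4X at 0.419 and RPS15A at 0.388. Among the lowest were RPS25 at −0.160, RPL29 at −0.014, ATP5B at 0.012 and RPS15 at 0.025. Of 998 windows, 58.5% were higher at D7, and 46.4% after rescaling. The largest positive window differences were at 1951 to 2000 of ACTG1, with 0.183 at H9 and 0.565 at D7, at 901 to 950 of RPL6, with 0.188 and 0.514, and at 1051 to 1100 of HNRNPA1, with 0.137 and 0.458. The largest negative ones were at 251 to 300 of RPS6, with 0.610 and 0.298, at 251 to 300 of RPL26, with 0.486 and 0.184, and at 1951 to 2000 of HSP90AA1, with 0.592 and 0.292. Rescaled, these differences were 0.341, 0.281 and 0.155, and −0.348, −0.333 and −0.361, so that of HNRNPA1 shrank from 0.321. The Gini index was higher at D7 in 39 of 83 transcripts.

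From D0 to D7, the rate was again higher in all transcripts compared, 85 of 85, with a median ratio of 2.23. The smallest log2 ratios were 0.29 for TUBB3 and for PTMA, 0.35 for MARCKSL1 and 0.36 for CRABP1, which were picked after their values were seen, and the largest were 1.85 for NPM1 and 1.70 for ATP5A1. VIM had 0.79. Scaled mean reactivity was higher at D7 in 65 of 85 transcripts, with a median difference of 0.024, and in 44 of 85 after rescaling. The largest positive difference was in 18S rRNA, at 0.210 and 0.362, followed by HNRNPA1 at 0.247 and 0.357, EEF1B2 at 0.295 and 0.404, RPS15A at 0.291 and 0.398, GSTP1 at 0.273 and 0.370, and HMGN2 at 0.248 and 0.344. HNRNPA1 turned to −0.095 after rescaling and HMGN2 to −0.001, while 18S rRNA kept 0.106 and EEF1B2, RPS15A and GSTP1 had 0.057, 0.034 and 0.061. The largest negative differences were in LDHB, at 0.390 and 0.297, ATP5B, at 0.369 and 0.291, H3F3A, at 0.315 and 0.240, RPL9, at 0.410 and 0.336, NPM1, at 0.390 and 0.321, and RPL26, at 0.389 and 0.330. All but H3F3A, at 0.009, kept their sign after rescaling, ATP5B at −0.027. LDHB and NPM1 were thus lower at D7 against both other stages on both scales.

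Ribosomal protein mRNAs had a median difference of 0.027 from D0 to D7, with 38 of 46 higher, at the 81.4th percentile of random lists, and 23 of 46 were higher after rescaling. Cytoskeletal mRNAs had a median of 0.040, with 7 of 8 higher, at the 89.7th percentile, and 3 of 8 were higher after rescaling. Their rates did not stand apart in this comparison, with a median log2 ratio of 1.16 at the 45.9th percentile. The glycolytic mRNAs were all lower at D7, GAPDH at 0.40 and 0.368 and TPI1 at 0.317 and 0.296. RPL4 had 0.318 and 0.345, RPL3 had 0.343 and 0.399, EEF1G had 0.350 and 0.34, GNB2L1 had 0.362 and 0.320, and YBX1 had 0.310 and 0.311. HSP90AA1 had 0.303 and 0.324, H2AFZ had 0.331 and 0.304, ATP5A1 had 0.255 and 0.323, FTL had 0.268 and 0.287, and FTH1 had 0.306 and 0.346. Rescaled, RPL4, HSP90AA1 and H2AFZ changed direction, at −0.028, −0.024 and 0.029, and ATP5A1 shrank to 0.0004. The other transcripts named in this paragraph kept their direction. Over all eligible transcripts of D0 to D7, 27 of 85 changed direction when rescaled.

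The median correlation between D0 and D7 without rRNA was 0.18 (95% interval 0.155 to 0.210), and 15.4% of 19751 positions differed by more than 0.5, against 20.2% after shuffling. After the rRNAs, RPS12 at 0.540, RPL21 at 0.460 and RPL41 at 0.408 were highest. RPL24 at −0.042, RPL26 at 0.008, RPS7 at 0.009, ATP5B at 0.012 and PRDX1 at 0.030 were lowest. Of 1036 windows, 59.7% were higher at D7, and 49.6% after rescaling. At 351 to 400 of RPL36 the mean reactivity was 0.114 at D0 and 0.554 at D7. There 14 of 14 positions were higher, a count that largely follows from picking windows by their difference. Mean reactivity was 0.162 and 0.532 at 401 to 450 of HMGN2, and 0.167 and 0.489 at 451 to 500 of DYNLL1. The largest negative differences were at 1451 to 1500 of ATP5B, with 0.445 and 0.131, at 401 to 450 of H2AFZ, with 0.473 and 0.185, and at 101 to 150 of RPL26, with 0.483 and 0.198. The rescaled differences were 0.429, 0.287 and 0.337, and −0.267, −0.266 and −0.308. The Gini index was higher at D7 in 35 of 85 transcripts.

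The balance between the bases that DMS modifies differed by stage. In scaled reactivity over the positions listed, cytosines were the more reactive base at H9 and D0, and adenines at D7. A was above C in mean reactivity in 33 of 222 transcripts at H9 (14.9%, exact 95% binomial interval 10.5 to 20.2%), in 16 of 190 at D0 (8.42%, 4.89 to 13.3%) and in 100 of 133 at D7 (75.2%, 67.0 to 82.3%). On the positions listed at all 3 stages, the shares were 45.1% (34.6 to 55.8%), 30.8% (21.5 to 41.3%) and 84.6% (75.5 to 91.3%) of 91 transcripts, so that at H9 the interval included 50%. The direction at D7 depended on the background subtraction. On the treated rate before subtraction A was above C in 1.5% of transcripts at D7, with means of 0.849% at A and 1.10% at C, against 0.569% and 1.01% at H9. The background-subtracted rate at A was 0.432% at H9, 0.374% at D0 and 0.709% at D7, and at C it was 0.519%, 0.494% and 0.663%. The intervals cover only the number of transcripts.

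**Figure D4:**
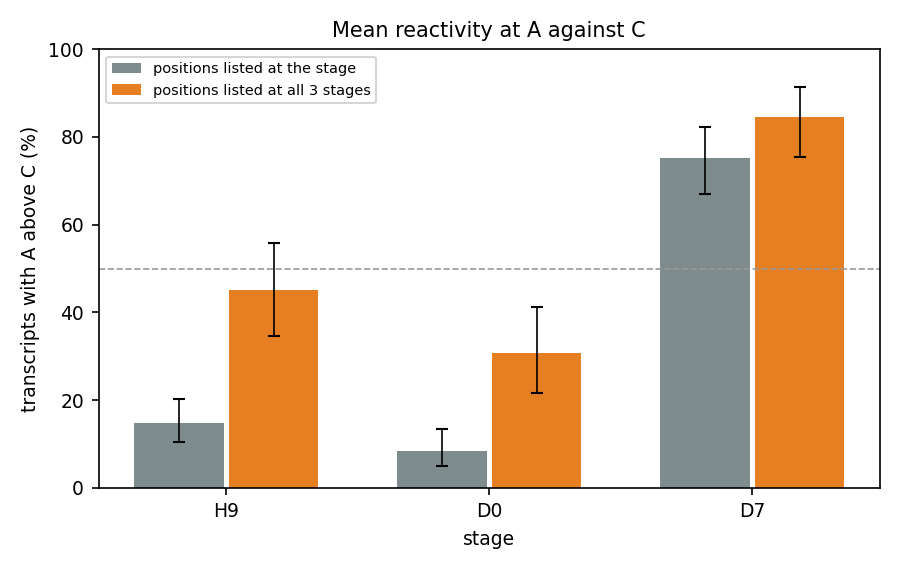
Share of transcripts (%) whose mean reactivity was higher at A than at C, by stage (x axis), for all positions listed at a stage (grey) and for positions listed at all 3 stages (orange), with exact 95% binomial intervals as error bars and a dashed line at 50%. D7 lies above 50% in both sets, and D0 lies below it in both.

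The control libraries carried a substantial share of the mutations. Averaged over listed positions, the control rate was 0.291% at H9, 0.226% at D0 and 0.271% at D7, and the DMS-treated rate was 0.761%, 0.653% and 0.960%. Treated rates exceeded control rates 2.61-fold, 2.89-fold and 3.54-fold, but only positions with a treated rate above the control rate are listed, so the direction is fixed by that filter. The background was higher at C than at A, at 0.488% against 0.137% at H9, 0.394% against 0.0945% at D0, and 0.442% against 0.140% at D7.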

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

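No paired analysis was possible because the deposited values are given per stage and carry no replicate number. For the same reason leaving out a replicate was not possible. A pseudocount and a linear scale apply only to the log-scale tests, which were not run, a cap at 1 and a limit to A and C positions change nothing in values that already have both, a threshold of 1 cannot be exceeded by a score between 0 and 1, and the comparison by transcript region was not run. Read depth is unknown and limits every value of a single position. Rescaling on shared positions, A or C positions alone, positions with a control rate of at most 0.2%, the unscaled rates and the positions shared by all 3 stages were chosen after seeing the data. A value was taken as moved when it left the 95% interval of the value reported, and for a single transcript when it fell below 50% of it. The cause of each move was not tested, except that the threshold of 0.25 is met by more positions by construction.

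Of 175 summary values under alternatives, 102 stayed within that interval, 67 moved and 6 changed sign. The share of transcripts with a higher mean reactivity at the second stage was 45.0% from H9 to D0 and kept within its interval under all 9 alternatives. From H9 to D7 it was 61.4%, and it moved to 44.6% with the stages scaled to the same median, 41.0% after rescaling on shared positions, 73.9% at A, 35.6% at C and 100% on the background-subtracted rate. From D0 to D7 it was 76.5%, and it moved to 63.3% with at least 200 positions, 40% with the same median, 51.8% after rescaling, 85.6% at A, 28.3% at C and 100% on the rate. The share of windows moved from 46.3% to 42.5% between H9 and D0 with at least 20 positions. From H9 to D7 it moved from 58.5% to 64.5% with at least 20 positions, 50.2% with the same median and 46.4% after rescaling. From D0 to D7 it moved from 59.7% to 63.1% in 100-nucleotide windows, 49.9% with the same median and 49.6% after rescaling.

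The share of positions that differed, 14.5%, 15.3% and 15.4% in the order H9 to D0, H9 to D7 and D0 to D7, was 39.8%, 41.8% and 42.2% at a threshold of 0.25. It was 15.3%, 16.1% and 16.1% at positions with a mean reactivity of at least 0.05, 16.6%, 17.4% and 16.9% after rescaling, 16.8%, 15.9% and 16.1% at C, and 10.2%, 12.8% and 12.3% at a low control rate. It moved to 13.0% at A from H9 to D0, and with the same median to 14.3% from H9 to D7 and 13.6% from D0 to D7.

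The median correlation without rRNA rose on the treated rate to 0.778, 0.585 and 0.624 in the same order. From H9 to D0 it moved to 0.169 as Spearman's rho, 0.145 at A, 0.247 at C and 0.231 at a low control rate, and from D0 to D7 to 0.142 at A, 0.225 at C and 0.212 at a low control rate. The share with a higher Gini index moved to 48.6% from H9 to D0 on the unscaled rate and to 60% from D0 to D7 with at least 200 positions.

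The median log2 ratio of the rate was −0.04 from H9 to D0, 0.012 at C and −0.12 for the treated rate. From H9 to D7 it was 1.12, and 1.22 at A, 0.94 at C, 1.20 at a low control rate and 0.72 for the treated rate. From D0 to D7 it was 1.16, and 1.29 at A, 0.91 at C, 1.30 at a low control rate and 0.79 for the treated rate. The share of transcripts with A above C moved at H9 to 27.5% with medians, 9.91% on the subtracted rate, 0.0% on the treated rate and 45.1% on positions shared by all 3 stages. At D0 it moved to 21.6% with medians, 0.526% on the treated rate and 30.8% on shared positions, and at D7 to 1.5% on the treated rate and 84.6% on shared positions.

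Among the lists, the median of the ribosomal protein mRNAs turned to −0.0033 with the same median and −0.0146 after rescaling from H9 to D7. From D0 to D7 it turned to −0.0067 with the same median and moved to 0.00026 after rescaling. The cytoskeleton list turned to −0.0062 from H9 to D0 with at least 50 positions and to −0.0143 from D0 to D7 after rescaling. Of the 36 largest differences of single transcripts, 7 changed sign after rescaling, 13 more fell below 50% of the value reported and 16 did neither. Under the other alternatives run 0 changed sign, and 5 of the 23 computed at C positions, 2 at A positions, 1 at a low control rate and 1 with medians over positions fell below 50%. Those that changed sign were RPL17 at −0.041 from H9 to D0, RPL17 at −0.074, HNRNPA1 at −0.040 and RPL23A at −0.018 from H9 to D7, and H3F3A at 0.0087, HNRNPA1 at −0.095 and HMGN2 at −0.0013 from D0 to D7.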

Other observations

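Among rRNA positions listed at all 3 stages, the 5 with the highest mean rate in each rRNA did not all follow the same course across stages. Numbered as in the table, position 1196 of 18S rRNA, an A, had a background-subtracted rate of 3.99% at H9, 3.90% at D0 and 6.01% at D7. Position 1471, a C, had 3.60%, 4.57% and 5.48%, position 1303, a C, had 3.63%, 3.77% and 4.74%, and position 568, a C, had 1.60%, 1.84% and 2.5%. Position 1859, an A, had 2.94%, 0.542% and 1.32%, on control rates of 0.442%, 0.281% and 0%. In 28S rRNA, position 4523, an A, had 10.6%, 12.3% and 12.9%, position 1964, an A, had 5.78%, 6.44% and 14.1%, and position 4252, a C, had 2.31%, 2.43% and 3.58%. Position 170, a C, had 0.835%, 2.69% and 3.39%. Position 4033, a C, had 3.77%, 2.98% and 0.569%, on control rates of 4.44%, 1.73% and 4.38%. Read depth at single positions is unknown, so the courses of positions 1859 and 4033 may rest on few mutated reads.

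The tests of a lower control rate, of modification across libraries, of the positions listed and their part in the contrast, of the control rate at C, of a library-wide A to C change and of subtraction noise were chosen after the results they bear on had been seen, and the 2 tests of read depth before.

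The background-subtracted rate was higher at D7 than at H9 in 83 of 83 transcripts. A fall of the control rate made up a median of 3.06% of the rise (95% interval of the median 1.10 to 4.88%), which argues against a lower background at D7 as its cause. If fewer reads at D7 had left only high rates in the table, the rise should vanish in the mRNAs with the finest listed rates, and in the 10 finest the median log2 ratio was 1.17, but with an interval from 0.46 to 1.34 that reaches below the bound of 0.5 set for exclusion. Across mRNAs the log2 ratio rose with the smallest rate listed at D7, with a Spearman rho of 0.263. That smallest rate and the ratio both draw on the D7 rates, so a positive rho can arise whatever the depth and cannot decide. The explanation by fewer reads therefore stays open. Stronger modification or mutation recovery across the D7 libraries may contribute, since 18S rRNA at 1.18 lay within the 10th to 90th percentile range of mRNAs, 0.72 to 1.44, but 28S rRNA at 0.29 did not, so 1 of the 2 rRNAs met it. A difference between the cells stays open and untested, because stage and library cannot be told apart without replicate values.

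In background-subtracted reactivity, A exceeded C in most transcripts at D7 and not at H9 or D0, and on the treated rate in 1.5% of transcripts at D7. The positions listed do not account for all of it, since on positions listed at all 3 stages A was above C in 84.6% of 91 transcripts at D7 (75.5 to 91.3%) and in 45.1% at H9 (34.6 to 55.8%). They go with part of the contrast, which in the same transcripts was smaller by 20.9 percentage points (8.79 to 33.0) than on all listed positions. Nor does the background at C, which fell from 0.389% to 0.354% at positions shared by H9 and D7, a change of −0.303 times the gap that opened between A and C. The log2 ratio of the A to the C rate rose from H9 to D7 by 0.42 in 18S rRNA (bootstrap interval over positions 0.18 to 0.62) and by 0.65 in 28S rRNA (0.34 to 0.97). A change of A against C signal across the D7 libraries as a whole is a candidate explanation, on 2 RNAs only, while a structural difference between the stages was not tested.

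Messenger RNA profiles of H9 and D0 correlated weakly, while 18S rRNA reached 0.909. Noise from subtracting the control rate could not be settled as a cause over all positions. Restricting to positions with a control rate of at most 0.2% at both stages raised the correlation by a median of 0.034 (0.011 to 0.054). That restriction favours A, whose control rate at H9 was 0.137% against 0.488% at C. Since the correlation was lower at A than at C, the small rise cannot decide the question. The treated rate before subtraction correlated with a median of 0.778 over all positions. The control rate correlated with a median of 0.829, so background shared by both stages enters that value. It therefore does not single out noise from subtraction. At the positions with a low control rate the treated rate reached 0.247 (0.218 to 0.30). The weak correlation there was thus present before subtraction, which argues against subtraction noise as its cause at those positions. At positions with a higher control rate subtraction noise stays open. Limited read depth is a candidate explanation. The smallest rate listed for a transcript served as a stand-in for depth, which the table does not give, and the correlation fell as that rate became coarser, with a Spearman rho of −0.454 across 109 mRNAs and −0.437 after accounting for the number of positions. The median correlation was 0.248 in the 36 mRNAs with the finest rates and 0.140 in the 37 with the coarsest. Real structural differences between the stages stay open, and mRNAs are not independent replicates.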
